A study of Homo sapiens with 4 samples.

How the data were processed

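Gene expression was measured with Affymetrix HG-U133 Plus 2 arrays in Saos-2 cells, a human osteosarcoma line without functional p53, taken 24 h after infection with 1 of 4 adenoviruses. The viruses carried GFP (the control), p53, TAp63γ or p63-53O, which the series' design text describes as a hybrid of p53 and p63. There were 4 arrays, 1 per virus, and each sample's group came from the labels.

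The deposited values are signal intensities on a linear scale, 1 per probe set. Per the submitters' processing notes they were made with GCOS for the GFP and p53 arrays and with MAS5 for the TAp63γ and p63-53O arrays, and no versions are given. The authors' values had a 2% trimmed mean of 500.1 on each array, and the scaling and any other normalization are not given in the sources used here. Detection calls, scanner files and a description of background correction were not used here. The different tool names divide the arrays into 2 processing sets, GFP with p53 and TAp63γ with p63-53O. Comparisons across the sets cannot separate the virus from any difference between the sets.

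Starting from the deposited intensities, each array was scaled again to a 2% trimmed mean of 500, which changed almost nothing. Values below a floor of 67.9, the 40th percentile of the scaled values of the 4 arrays pooled, were set to the floor, and log2 was taken. Differences of these log2 values are given as log2 ratios or as folds. A fold against an array at the floor is a lower bound and is written "at least". Of the 54675 probe sets, 41097 had 1 gene symbol in the platform annotation of 2016, 1801 had several and 11777 had none. Symbols were looked up again through the gene ID in a RefSeq table of assembly GRCh38.p14, which held the gene ID of 41043 of the 41097 probe sets and changed 0 symbols. The 62 control probe sets served only as checks of array quality. Each of the 19775 genes was represented by its probe set with the highest mean signal over the 4 arrays. The 16572 genes above the floor on at least 1 array were compared. The levels of the introduced genes are not reported here.

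With 1 array per virus no statistical test of a condition was possible. Differences are therefore described by size, no p-value is given, and the number of arrays limits the precision of every value. The threshold for counts was 2-fold. Where several probe sets of a gene were above the floor on an array of the pair, the SD of their log2 ratios is given as a technical spread within the 2 arrays; it does not replace replicates. The chance level was simulated with 100 sets of 4 unchanged arrays, whose noise at each signal level was the spread of log2 ratios between the p63-53O and TAp63γ arrays. That spread holds any real differences between these arrays and leaves out any added noise between the processing sets, so the simulated levels may lie above or below the true chance levels. The simulation assumes normally distributed noise.

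The design, the alternatives and 18 gene lists holding 516 genes were fixed before the data were examined. A total of 443 of these genes were measured, in 17 lists; the remaining list held only the 2 introduced genes. The median log2 ratio of each list was placed among the medians of 10000 random lists of the same size matched on mean expression in 10 bins, which describes these arrays and is not a test of the conditions. The genes named in the text were drawn from a fixed rule. It took the introduced genes, CDKN1A and MDM2 in comparisons with GFP, and in each comparison the 8 highest and 6 lowest ratios among genes above the floor on both arrays. In comparisons with GFP it added the 6 brightest genes at least 4-fold above a GFP array at the floor and the 4 brightest in the other direction. From each list it took up to 3 members with the largest absolute ratio, and for the hybrid alone the 10 genes with the largest margin over the other 3 arrays. Except for the first genes and the list members, genes with another measured probe set at least 2-fold the other way were passed over. Not every gene the rule gave is printed.

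The steps were tested on simulated data for the comparison of p53 with GFP, over 15864 genes. Of 100 genes changed 4-fold, 98% were called in the right direction at 2-fold, as were 49% of 100 genes changed exactly 2-fold, and 12.3% of the unchanged genes were called in either direction. The changed genes were drawn only from those with a GFP signal more than 4-fold above the floor. Their shares therefore do not cover dimmer genes. The alternatives were quantile normalization, equal medians, the values as deposited, floors at the 20th and 60th percentiles, the mean over all probe sets of a gene, probe sets without the marks of shared sequence in their IDs, a 3-fold threshold, and genes above the floor on all 4 arrays. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.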

Results

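The data set holds 4 expression arrays of Saos-2 cells, collected 24 h after infection with an adenovirus carrying GFP, p53, TAp63γ or the p63-53O hybrid. p53 and TAp63γ are related transcription factors that bind similar DNA sites. The series title sets the question of which genes respond specifically to the hybrid, so each protein was compared with GFP and the hybrid was compared with both parent proteins. Each virus was measured on 1 array, so no value below carries a replicate error. The arrays had equal trimmed means but unequal low signals. The median probe set read 82.2 on the GFP array, 102.0 on the p53 array, 108.8 on the TAp63γ array and 123.7 on the p63-53O array. Of the 16572 genes compared, 73.8% were above the floor with GFP, 82.9% with p53, 86.5% with TAp63γ and 91.3% with p63-53O. The 3' to 5' signal ratio of GAPDH, a sign of RNA integrity, lay between 0.952 and 1.02 on the 4 arrays, and that of ACTB between 1.28 and 1.43. The 18 hybridisation control probe sets read a median of 0.24 higher on the log2 scale with p53 than with GFP, 0.37 higher with TAp63γ and 0.36 higher with the hybrid. The median log2 ratio of all genes was 0.21 for the hybrid against GFP and became 0.04 after quantile normalization and -0.10 with equal array medians. With equal medians it went from 0.06 to -0.11 for the hybrid against p53 and from 0.05 to -0.07 for the hybrid against TAp63γ.

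Against GFP, p53 was accompanied by higher signals of its textbook target genes and lower signals of mitotic genes. CDKN1A, the cyclin-dependent kinase inhibitor p21, read 32790 with p53 and 1428 with GFP, a 23.0-fold difference. MDM2, the ubiquitin ligase that limits p53, was 10.1-fold higher, with all 10 measured probe sets higher by at least 2.33 on the log2 scale (SD 1.37). GDF15, a stress-induced cytokine, was 208-fold higher on its main probe set and 1.18 higher on the log2 scale on its other one. TP53I3, a quinone oxidoreductase gene, was 34.8-fold higher. Among genes at the floor with GFP, CAV1, which encodes a caveolar coat protein, was at least 345-fold higher, PRKCZ, an atypical protein kinase C, at least 256-fold higher, and CLCA2 at least 104-fold higher.

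The 3 lists of p53 targets all read higher with p53. Of 29 measured arrest and signalling genes, 25 were at least 2-fold higher with p53, 1 was lower and the median log2 ratio was 2.76. SFN, which encodes 14-3-3 sigma, was at least 48.7-fold higher and PHLDA3 was 25.9-fold higher. Of 27 measured apoptosis genes, 19 were higher and 0 lower, with a median of 2.19. CASP1, the inflammatory caspase, was 18.3-fold higher (SD 0.86 in log2 over 5 probe sets), and BIK, a BH3-only protein, was at least 21.0-fold higher. Of 26 measured DNA repair and metabolism genes, 19 were higher and 0 lower, with a median of 2.18. CYFIP2, PLTP and SPATA18 were 62.4-fold, 31.7-fold and 30.5-fold higher. Each of these medians lay at percentile 100 of the random lists, whose medians for the arrest list ranged from -0.27 to 0.43 over the central 95%.

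Of 40 measured G2 and mitosis genes, 35 were at least 2-fold lower with p53 and 1 was higher, with a median log2 ratio of -1.81. The mitotic kinase gene TTK was 8.62-fold lower, the kinesin gene CENPE 7.83-fold lower and DLGAP5 7.62-fold lower. In contrast, 5 of 39 G1/S and DNA replication genes were lower and 1 was higher, with a median of -0.16 at percentile 8.36. RRM2, a subunit of ribonucleotide reductase, was 3.66-fold lower and CDT1, a replication licensing factor, 4.34-fold higher. Of 40 epidermal and epithelial genes, 17 were higher and 2 lower, with a median of 0.78, among them the integrin gene ITGA6 at least 29.0-fold and the desmosomal cadherin gene DSC3 at least 18.2-fold higher. Of 25 measured NF-kB and cytokine genes, 10 were higher and 0 lower, with a median of 0.65 at percentile 99.95. The macrophage growth factor gene CSF1 was 11.5-fold higher and LIF 6.73-fold higher. Of 35 interferon response genes, 10 were higher and 5 lower, and the median of 0.26, which turned to -0.01 with equal array medians, lay within the range of random lists. TAP1, a peptide transporter of antigen presentation, was 12.0-fold higher.

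In all, 2125 genes were at least 2-fold higher and 1345 at least 2-fold lower with p53 than with GFP, and 600 and 128 differed by 4-fold. The simulated unchanged arrays gave a mean of 802 higher and 800.4 lower at 2-fold and 32.4 and 33.9 at 4-fold. Of the genes at least 2-fold higher, 1069 had a second measured probe set, and 60.4% of these probe sets were also at least 2-fold higher, against 12.9% of all second probe sets. With equal array medians the split turned to 1593 higher and 2439 lower. This comparison lay within 1 processing set.

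**Figure D1:**
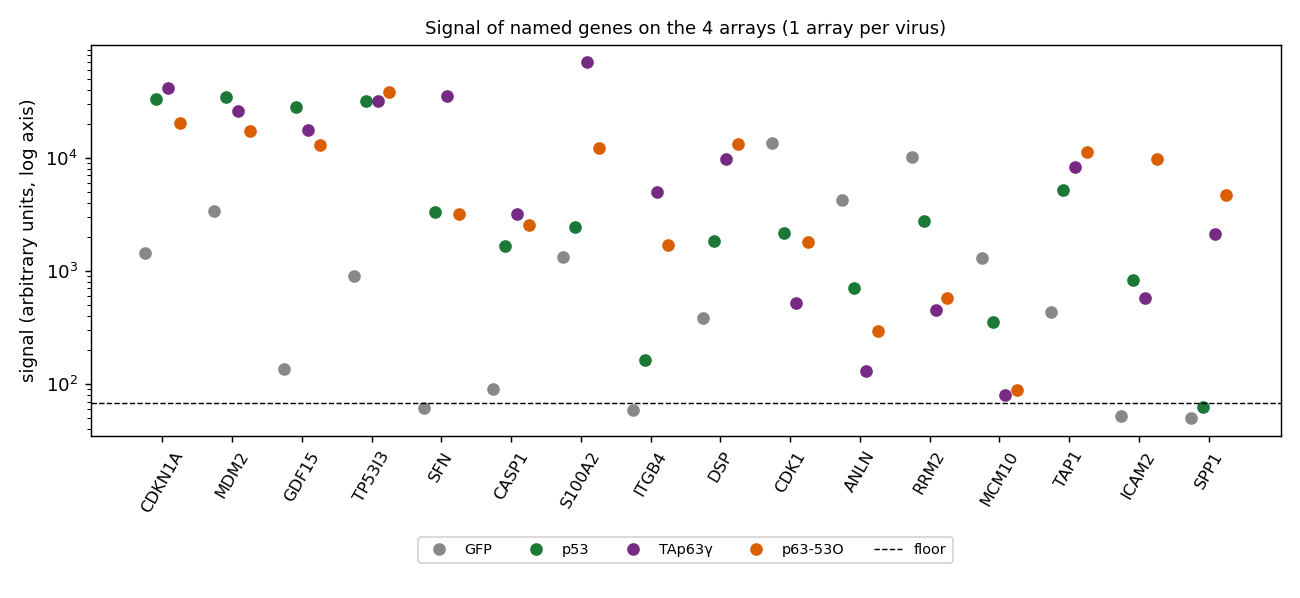
Signal (arbitrary units, log axis) of 16 named genes on the GFP, p53, TAp63γ and p63-53O arrays, 1 point per array, with the floor of 67.9 as a dashed line. CDKN1A read 1428 with GFP and between 20160 and 41568 with the other viruses, and SFN and S100A2 were brightest with TAp63γ.

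TAp63γ was accompanied by higher signals of the p53 target lists too, and by a lower signal of both mitotic and replication genes. CDKN1A was 29.1-fold and MDM2 7.52-fold higher than with GFP. SFN read 35026, at least 516-fold higher, and CAV1 was at least 496-fold higher. RNF144B, a ubiquitin ligase gene, was 205-fold higher (SD 0.92 in log2 over 4 probe sets), and MET, the hepatocyte growth factor receptor, 203-fold higher (SD 1.85 over 4). At the other end, the peptidase inhibitor gene PI15 was 39.4-fold lower on its main probe set (SD 0.03 over 2), and BMP4, a bone morphogenetic protein, was at least 27.3-fold lower.

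Of the p53 targets, 20 of 29 arrest and signalling genes were higher and 2 lower with TAp63γ, with a median log2 ratio of 2.07. For apoptosis genes the counts were 21 higher and 0 lower of 27, with a median of 2.12, and for repair and metabolism genes 18 higher and 2 lower of 26, also with a median of 2.12. Of 40 epidermal and epithelial genes, 22 were higher and 3 lower, with a median of 1.19. S100A2, a calcium-binding protein of basal epithelium, was 52.0-fold higher, the hemidesmosome integrin ITGB4 at least 72.7-fold on its main probe set (SD 2.72 in log2 over 4, the lowest 0.02) and WNT4 at least 44.2-fold higher. Of 40 G2 and mitosis genes, 34 were lower and 1 higher, with a median of -3.22, including a 32.2-fold lower ANLN and a 25.6-fold lower CDK1, the mitotic cyclin-dependent kinase (SD 1.38 over 4 probe sets). Of 39 G1/S and replication genes, 22 were lower and 2 higher, with a median of -1.31, including a 22.2-fold lower RRM2 and a 16.2-fold lower MCM10. Each of these 6 medians lay at percentile 100 or 0 of the random lists. For interferon response genes the counts were 12 higher and 7 lower of 35, with a median of 0.48 at percentile 97.54, and for NF-kB and cytokine genes 9 higher and 0 lower of 25, with a median of 0.47 at percentile 93.9. TAP1 was 19.2-fold and the transcription factor gene IRF1 10.7-fold higher.

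In all, 3190 genes were at least 2-fold higher and 2705 lower with TAp63γ than with GFP. With equal array medians these counts were 2241 and 3994. The 2 arrays belong to different processing sets, so the virus and the set cannot be told apart here.

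The hybrid was accompanied by the highest number of differing genes, with 4155 at least 2-fold higher and 2868 lower than with GFP. RASSF4, a Ras-association domain gene, was 134-fold higher (SD 0.96 in log2 over 3 probe sets) and AQP3, a water and glycerol channel, 82.6-fold higher. CDKN1A was 14.1-fold and MDM2 5.04-fold higher. PRKCZ was at least 528-fold and ICAM2, a cell adhesion molecule, at least 145-fold higher. RAD51AP1, a homologous recombination gene, was 35.8-fold lower and RRM2 17.4-fold lower.

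Among p53 targets, 20 of 29 arrest and signalling genes were higher and 2 lower with the hybrid, with a median log2 ratio of 2.13. For apoptosis genes the counts were 19 higher and 1 lower of 27, with a median of 2.06, and for repair and metabolism genes 18 higher and 2 lower of 26, with a median of 1.76. TP53I3 was 41.7-fold, DDB2, a nucleotide excision repair factor, 21.9-fold and BIK at least 74.9-fold higher. Of 40 epidermal and epithelial genes, 25 were higher and 2 lower, with a median of 1.49; the desmosome gene DSP was 34.6-fold higher and ITGA6 at least 57.7-fold higher. Of 40 G2 and mitosis genes, 31 were lower and 1 higher, with a median of -2.39, and of 39 G1/S and replication genes, 22 were lower and 2 higher, with a median of -1.39. The cyclin gene CCNE2 was 11.4-fold lower. Interferon response genes were higher in 16 and lower in 7 of 35, with a median of 0.93 at percentile 99.9. TAP1 was 26.0-fold, MX1 12.2-fold and the ISG15 protease gene USP18 12.4-fold higher. NF-kB and cytokine genes were higher in 8 and lower in 0 of 25, with a median of 0.69 at percentile 91.8. With equal array medians the medians against GFP were 1.54 for arrest, 1.47 for apoptosis, 1.27 for repair and metabolism, 1.03 for epidermal and epithelial, -2.98 for G2 and mitosis, -1.98 for G1/S and replication, 0.35 for interferon response and 0.36 for NF-kB and cytokine genes.

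Of the markers of other cell types, the endothelial list read higher with the hybrid than random lists, and the blood cell and the kidney and neural lists lay within the random range. Of 10 measured endothelial markers, 6 were at least 2-fold higher and 0 lower, with a median of 1.03 at percentile 99.3, and VWF was at least 10.8-fold higher at a signal of 735. VWF, ROBO4, TEK, ERG and PLVAP were below the floor with GFP and so could not read lower. ROBO4, TEK and ERG read only 208, 140 and 138 with the hybrid, whose array had the highest low signals. PECAM1 and EGFL7, above the floor with GFP, were 2.35-fold and 2.22-fold higher. For blood cell markers the counts were 4 higher and 0 lower of 12, with a median of 0.75 at percentile 85.3, and for kidney epithelial and neural markers 4 higher and 1 lower of 10, with a median of 0.71 at percentile 83.7 that became 0.12 with equal array medians. With equal array medians the counts of all genes were 2543 higher and 4623 lower. The hybrid and GFP arrays belong to different processing sets.

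**Figure D2:**
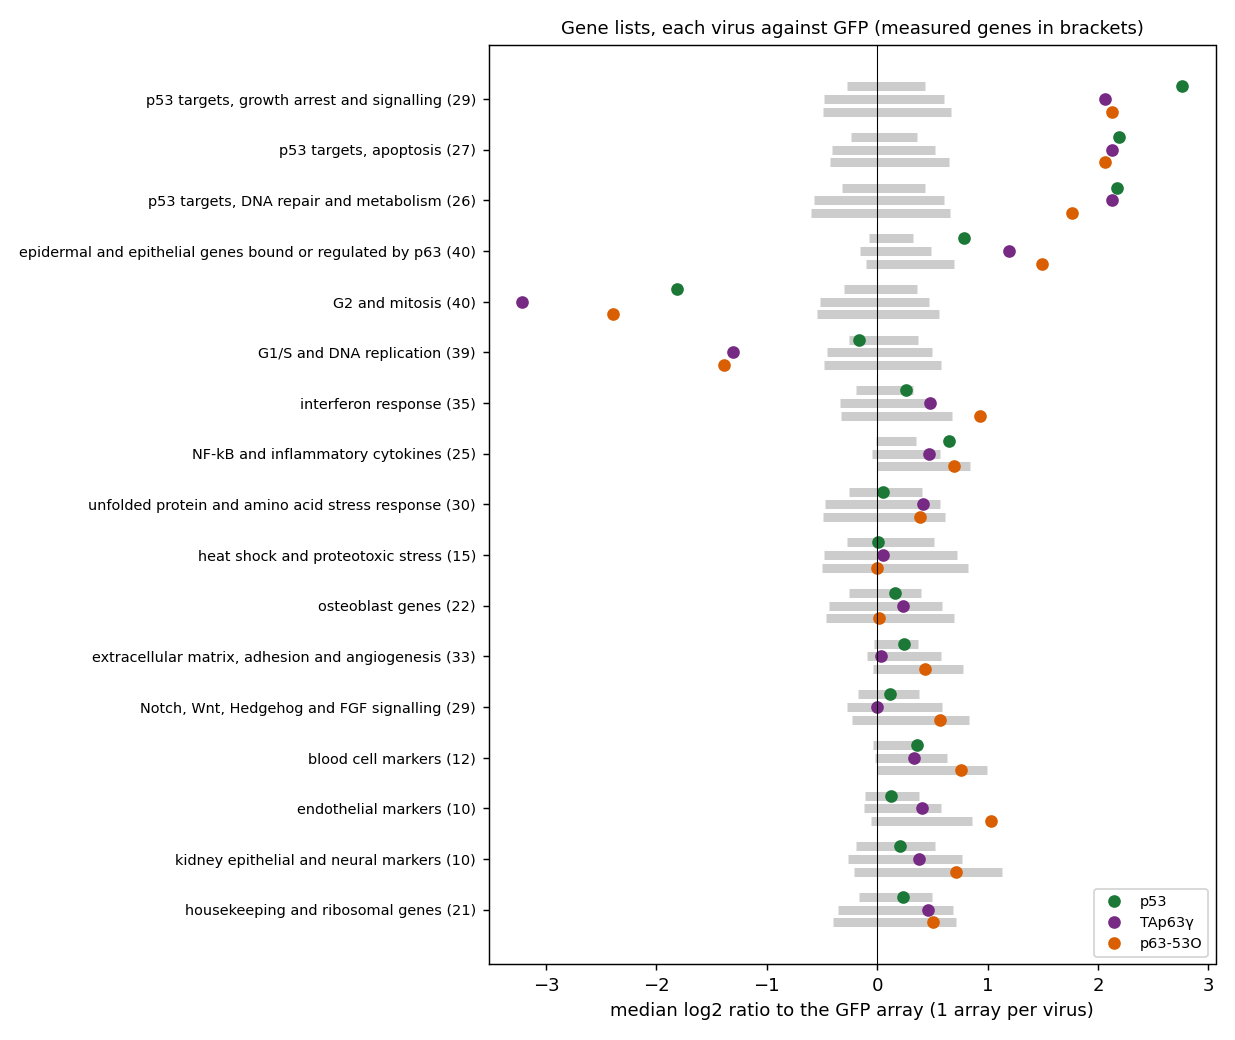
Median log2 ratio to the GFP array (x axis) of each gene list (y axis, number of measured genes in brackets) for p53, TAp63γ and p63-53O, 1 array per virus, with grey bars for the central 95% of random lists matched on expression. The 3 p53 target lists lie between 1.76 and 2.76 for each virus, and the G2 and mitosis list lies between -3.22 and -1.81.

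The 3 responses overlapped. Of the 2125 genes higher with p53, 1673 were also higher with the hybrid and 1511 also higher with TAp63γ, whereas independent lists of these sizes would share 533 and 409. TAp63γ and the hybrid shared 2490 higher and 2107 lower genes, against 799.8 and 468 for independent lists. Across genes, which are not independent replicates, the log2 ratios to GFP correlated with Pearson's r of 0.77 for p53 and TAp63γ (Spearman's rho 0.73), 0.76 for p53 and the hybrid (rho 0.72), and 0.86 for TAp63γ and the hybrid (rho 0.82). All 3 ratios share the GFP array. Unchanged arrays simulated with that sharing gave a mean r of 0.50, a covariance of 0.178 with 148 shared higher and 331 shared lower genes, and the observed covariances were 0.919, 0.974 and 1.56. Part of the overlap may come from the shared control, which is a single array and could not be divided. In total 1378 genes, among them CDKN1A and GDF15, were at least 2-fold higher with each of the 3 viruses than with GFP, and 1029 were lower.

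Set directly against p53, the hybrid showed lower medians of the arrest, repair, replication and mitotic lists and a higher median of the epithelial list. Most arrest, repair and mitotic genes differed by less than 2-fold. Of 29 arrest and signalling genes, 1 was at least 2-fold higher and 8 were lower with the hybrid, with a median log2 ratio of -0.47 at percentile 0.93. Of 26 repair and metabolism genes, 1 was higher and 8 lower, with a median of -0.58 at percentile 0.42. TRIM22 was 5.41-fold lower and SCO2, a cytochrome c oxidase assembly factor, 3.53-fold lower. Apoptosis genes were 4 higher and 4 lower of 27, with a median of 0.10 that became -0.15 with equal array medians; the death receptor gene FAS was 3.10-fold lower (SD 0.39 in log2 over 5 probe sets) and BIK 3.56-fold higher. G1/S and replication genes were 1 higher and 21 lower of 39, with a median of -1.15; MCM3, a subunit of the replicative helicase, was 5.97-fold lower and CCNE2 5.48-fold lower. G2 and mitosis genes were 3 higher, 6 lower and 31 between of 40, with a median of -0.44 at percentile 1.24. Among the higher ones, NDC80 was 4.05-fold and CDC20 3.16-fold higher. Epidermal and epithelial genes were 15 higher and 3 lower of 40, with a median of 0.70 at percentile 100. Interferon response genes were 12 higher and 2 lower of 35, with a median of 0.31 at percentile 95.8, and NF-kB and cytokine genes 1 higher and 5 lower of 25, with a median of 0.00. ITGB4 was 10.4-fold (SD 1.44 in log2 over 4 probe sets), DSP 7.11-fold and S100A2 5.05-fold higher than with p53. Outside the lists, the collagen genes COL2A1 and COL8A2 were 28.9-fold and 25.8-fold higher and CEMIP 27.9-fold higher, and PADI4, a peptidylarginine deiminase, was 11.9-fold lower. In all, 2308 genes were higher and 1599 lower, and with equal array medians 1469 and 2597. These arrays belong to different processing sets.

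TAp63γ against p53 showed lower cell cycle genes and higher epithelial genes. Of 40 G2 and mitosis genes, 1 was at least 2-fold higher and 25 were lower, with a median log2 ratio of -1.25, and of 39 G1/S and replication genes, 1 was higher and 18 lower, with a median of -0.94. RRM2 was 6.08-fold and ANLN 5.36-fold lower. Epidermal and epithelial genes were 12 higher and 5 lower of 40, with a median of 0.56; S100A2 was 28.6-fold and SFN 10.6-fold higher. The 3 lists of p53 targets lay within the random range. Their medians were -0.27 for arrest, 0.03 for apoptosis and -0.19 for repair and metabolism genes. With equal array medians the apoptosis median turned to -0.06. The crystallin gene CRYBA2 was 73.2-fold higher. In all, 1525 genes were higher and 1606 lower, between arrays of different processing sets. The number higher was 2814 with the floor at the 20th percentile, 998 with it at the 60th and 937 among genes above the floor on all 4 arrays, and the number lower was 1063 with the mean over all probe sets of a gene.

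**Figure D3:**
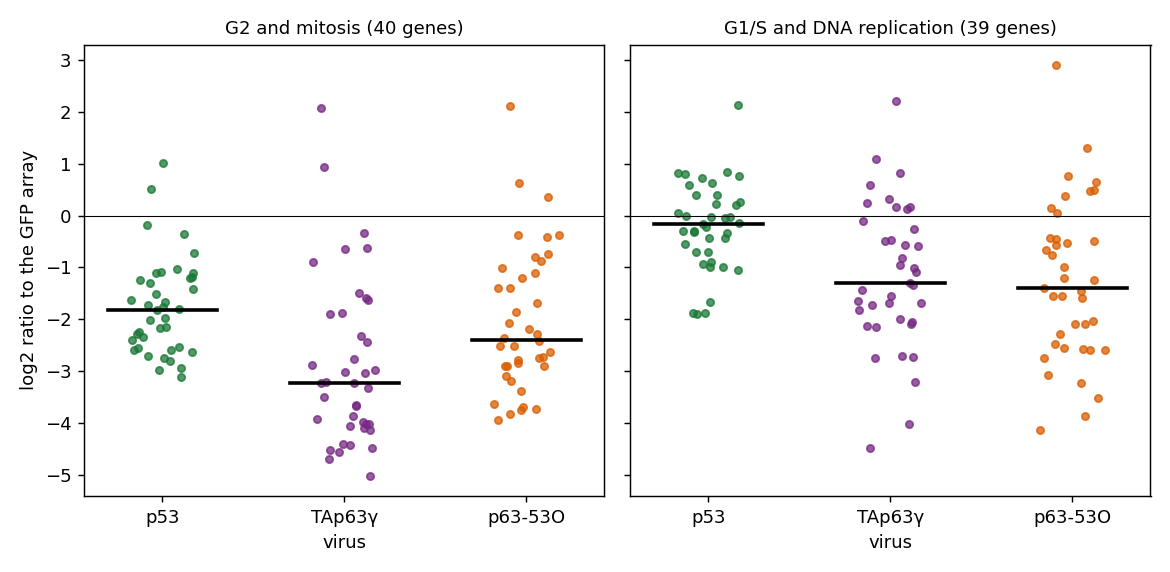
Log2 ratio to the GFP array (y axis) of each G2 and mitosis gene (left, 40 genes) and each G1/S and DNA replication gene (right, 39 genes) for p53, TAp63γ and p63-53O (x axis), 1 array per virus. Points are genes and bars are list medians, which are -1.81, -3.22 and -2.39 on the left and -0.16, -1.31 and -1.39 on the right.

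The hybrid and TAp63γ arrays belong to the same processing set, and their log2 signals correlated across probe sets with r of 0.890, against 0.885 for TAp63γ and p53, 0.876 for p53 and GFP, 0.874 for the hybrid and p53, 0.827 for TAp63γ and GFP and 0.805 for the hybrid and GFP. Mitotic genes read higher with the hybrid: of 40 G2 and mitosis genes, 17 were at least 2-fold higher than with TAp63γ and 0 lower, with a median log2 ratio of 0.87 at percentile 100. The kinetochore gene NDC80 was 9.56-fold and CDK1 3.43-fold higher (SD 0.46 in log2 over 3 probe sets). Replication genes did not separate the arrays, with 1 higher and 4 lower of 39 and a median of -0.03. SFN was 11.0-fold lower with the hybrid (SD 0.28 over 3 probe sets), S100A2 5.67-fold lower and the growth factor gene TGFB1 4.55-fold lower. Among other genes, the crystallin gene CRYBA2 was 51.0-fold lower, CCN5 12.2-fold lower, the Notch effector HES1 8.68-fold lower (SD 1.23 over 2 probe sets) and the corepressor TLE3 8.51-fold lower (SD 0.33 over 4 probe sets). Arrest and signalling genes were 3 higher and 3 lower of 29, with a median of -0.34 at percentile 0.23, apoptosis genes 1 higher and 4 lower of 27 with a median of -0.12, and repair and metabolism genes 2 higher and 2 lower of 26 with a median of -0.19. Epidermal and epithelial genes were 9 higher and 5 lower of 40 with a median of 0.05, which turned to -0.14 with equal array medians. Interferon response genes were 7 higher and 3 lower of 35, with a median of 0.50 at percentile 99.9; IFIT1 was 5.40-fold higher and IRF1 3.64-fold lower. NF-kB and cytokine genes were 2 higher and 3 lower of 25, and IL6 was 7.02-fold lower. In all, 1686 genes were higher and 734 lower with the hybrid, of which 477 of the higher ones were at the floor with TAp63γ. With equal array medians these counts were 1097 and 1089. The simulated noise was taken from the spread of this same pair, so the simulation gives no separate chance level for these counts.

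Genes higher or lower with the hybrid alone were counted as those at least 2-fold above, or below, each of the other 3 arrays. There were 816 such genes above and 211 below, and with equal array medians 421 and 421. By the same rule 173 genes were above and 45 below with p53 alone, and 250 and 223 with TAp63γ alone. The 10 genes with the largest margin over the other arrays were ABCC8, ICAM2, TNS1, CACNA1A, SLCO2B1, GATA5, CST11, CNGA3, IFNLR1 and IL2RB. ICAM2 read 9831 with the hybrid, 830 with p53 and 575 with TAp63γ, and was below the floor with GFP, so that the hybrid exceeded the nearest array 11.8-fold (SD 0.51 in log2 over 2 probe sets). ABCC8, the sulfonylurea receptor, read 945 with the hybrid and was below the floor on the other 3 arrays, a difference of at least 13.9-fold. CACNA1A, a calcium channel subunit, read 2006 with the hybrid and between 81.2 and 194 elsewhere, although 1 of its 3 probe sets lay at -0.05 on the log2 scale against GFP. SLCO2B1, an organic anion transporter, read 2547 with the hybrid and 249 with p53 and 83 with GFP, and was below the floor with TAp63γ. The median signal of the 816 genes with the hybrid was 363, and 187 of them were below the floor on all 3 other arrays. Simulated unchanged arrays gave a mean of 208 genes above and 50.3 below by this rule. Their noise was taken from the spread between the hybrid and TAp63γ arrays, so these means are no separate chance level for the hybrid.

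More genes set TAp63γ and the hybrid apart from the other arrays than any other pair. Both TAp63γ and the hybrid exceeded both GFP and p53 at least 2-fold for 806 genes and lay below both for 491. The p53 and hybrid arrays together exceeded the other 2 for 155 genes and lay below them for 10, and the p53 and TAp63γ arrays for 26 and 30. S100A2 read 69415 with TAp63γ and 12245 with the hybrid, against 2426 with p53 and 1335 with GFP. ITGB4 read 4939 and 1700, against 164 with p53 and a signal below the floor with GFP. The arrays that form the first of these pairs are also those of 1 processing set. Between the pairs of arrays that share no array, the log2 ratios of p53 to GFP and of the hybrid to TAp63γ correlated across genes with r of 0.083 (rho 0.10), and those of the hybrid to GFP and of TAp63γ to p53 with r of 0.50 (rho 0.48). The first pair of ratios lies within the processing sets. Both ratios of the second pair cross the sets in the same direction, so a difference between the sets could add to their correlation.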

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

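The tests of array scaling and of processing set for the replication genes were chosen after the result was seen, as were the resampled ranges of the scaling tests, and the other tests in this part before it. The outcomes written beforehand named no interval. The exact interval for the hybrid alone and the resampled range for bright signals were not part of them. Without these intervals, the values met the outcomes written for unequal low signals and for compression not being the cause, which is not taken as deciding either. The resampled ranges in this part take list members as independent and hold no error between arrays.

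Signal outside the comparisons came from the 13522 probe sets without a single named gene. Of these, 120 read at least 4-fold above the GFP array with p53, 264 with TAp63γ and 339 with p63-53O, while 35, 158 and 193 read at least 4-fold below it. They were singled out because no comparison of named genes used them.

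The first pattern is that more genes were higher than lower with the hybrid alone, 816 against 211, a ratio of 3.87. The counting rule can give such a ratio with no change, since unchanged simulated arrays gave a mean of 208 higher and 50.3 lower. Their noise came from the spread between the hybrid and TAp63γ arrays, and they lack the unequal low signals of the real arrays. The simulation therefore gives no separate chance level for the hybrid. On the real arrays the same rule gave 173 and 45 for p53 alone (ratio 3.84), 250 and 223 for TAp63γ (1.12) and 1029 and 1378 for GFP (0.747). The ratio for the hybrid was 2.28 after quantile normalization (exact 95% interval 1.98 to 2.63, for counting error only) and 1 with equal array medians. Among genes above the floor on all 4 arrays, 273 were higher and 173 lower with the hybrid alone. No value without change was computed under these settings, so they do not decide whether unequal low signals contribute. Noise of single probe sets is argued against as the whole source of the higher readings: 81.0% of 315 second probe sets of these genes read highest on the hybrid array, which is 2.75 times the 29.4% among all 8359 second probe sets. At 2-fold over each other array, the rule that called the genes, the shares were 35.9% and 3.29%, so most second probe sets did not repeat the call. The shares among all second probe sets were not matched on signal. A lift of low signals on the hybrid array was therefore not separated. No biological explanation was tested.

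The second pattern is the lower signal of G1/S and replication genes with TAp63γ and the hybrid than with p53, with a median log2 ratio of -0.94 for TAp63γ and -1.15 for the hybrid. For TAp63γ against p53, array scaling is argued against as the whole source. The list median minus the median of all genes was -0.93 at its nearest to 0 over the 3 scalings, and resampling the members gave no upper limit above -0.72. A factor for a whole array shifts the list and all genes alike. Only quantile normalization, which gave -0.93, could therefore have changed this difference much. The hybrid was not tested in this way. The processing set of the arrays cannot be told apart from the protein, as 0 viruses were measured in both sets. A difference between the proteins stays open for the same reason, and was not tested.

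The third pattern is that p53 target genes were, on balance, lower with the hybrid than with p53, by a median log2 ratio of -0.28 over the 82 members of the 3 lists, of which 57 lay below 0; the medians were -0.47 for arrest genes, -0.58 for repair genes and 0.10 for apoptosis genes, which turned to -0.15 with equal array medians. Quantile normalization did not remove the difference for these 82 members, but this does not exclude array scaling as a source. The outcome set beforehand for scaling as the cause was a median of 0 or higher after quantile normalization or with equal array medians. Equal array medians could not have given it. The median probe set read 123.7 with the hybrid and 102.0 with p53, so this setting lowers these ratios. The medians were -0.29 (resampled range -0.54 to -0.16) and -0.55 (-0.85 to -0.41), against -0.28 (-0.57 to -0.14) for the main value. Only quantile normalization could have given that outcome, and its median stayed below 0. A stricter rule for the resampled ranges, added after the result was seen, was not met, so scaling stays open. Compression of bright signals stays open: the 48 members below the 95th percentile of p53 signals had a median of -0.22, but resampling these members gave a range of -0.47 to 0.10. These members were chosen by their p53 signal, the denominator of the ratio, and this choice alone can raise their ratios. The hybrid and p53 arrays belong to different processing sets, so the set cannot be told apart from the protein here either. A difference in the amount of protein made from each virus may account for the pattern as well as a difference in activity, and neither was tested.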

How the results depend on the processing

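No paired analysis was possible because each virus was measured on 1 array. Over all alternatives, 77 of 126 counts of genes stayed within 1.5 times the main count and 669 of 714 list medians moved little. Of 2996 ratios of named genes 2390 moved little, 602 moved and 4 changed sign. A value moved little if it shifted by less than the median SD over probe sets of its comparison, which lay between 0.32 and 0.45. Sign changes were counted only for gene ratios of at least 2-fold and for list medians outside the random range. Other values that turned sign are counted among those that moved or moved little. Quantile normalization and probe sets without marks of shared sequence left every count within 1.5 times. The values as deposited differ from the main ones by almost nothing and test nothing. The totals above still include this setting, which gave 14 counts, 102 list medians and 432 gene ratios, all among those that stayed or moved little. The 4 changes of sign came with probe sets without marks of shared sequence, where HBB read -0.46 with TAp63γ against GFP, THBS1 0.079 with p53 against GFP, and RBM47 0.14 and TNIP1 0.93 with the hybrid against p53; the cause was not tested. Counts that moved follow. With equal array medians, which shift all ratios, 2439 genes were lower with p53 than with GFP, 2543 higher and 4623 lower with the hybrid than with GFP, 1469 higher and 2597 lower than with p53, 1097 higher than with TAp63γ, and 421 higher and 421 lower with the hybrid alone. With the floor at the 20th percentile, which keeps dimmer signals, 3824 genes were higher with p53 than with GFP, 5206 with TAp63γ and 6344 with the hybrid; the hybrid gave 3780 higher than p53, 2931 higher and 1558 lower than TAp63γ, and 1375 higher and 371 lower alone, and TAp63γ gave 2814 higher than p53. With the floor at the 60th percentile the hybrid gave 2616 higher than GFP, 1372 higher than p53, 908 higher and 449 lower than TAp63γ, and 421 higher and 128 lower alone, and TAp63γ gave 998 higher than p53. With genes above the floor on all 4 arrays, a smaller set, it gave 2552 higher than GFP, 1201 higher than p53, 860 higher and 482 lower than TAp63γ, and 273 higher alone, and TAp63γ gave 937 higher than p53. With the mean over all probe sets of a gene, 896 genes were lower with p53 than with GFP, and the hybrid gave 1042 lower than p53, 477 lower than TAp63γ and 111 lower alone, and TAp63γ gave 1063 lower than p53; the cause was not tested. At 3-fold, a stricter threshold, p53 gave 993 higher and 347 lower than GFP, TAp63γ 1673 and 1366, and the hybrid 2275 and 1513; the hybrid gave 925 and 448 against p53, 513 and 169 against TAp63γ, and 203 and 35 alone, and TAp63γ gave 580 and 521 against p53.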

Other observations

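Stress genes included large single differences although their lists as wholes lay within the range of random lists. Of 30 genes of the unfolded protein and amino acid stress response, 6 were at least 2-fold higher than with GFP and 2 lower with p53, 9 and 7 with TAp63γ, and 11 and 4 with the hybrid, with medians of 0.06, 0.42 and 0.39; with equal array medians those for p53 and the hybrid turned to -0.26 and -0.20. CHAC1, a glutathione-degrading enzyme, was 17.5-fold higher with p53 and 7.71-fold higher with the hybrid, and the transcription factor gene ATF3 was 10.4-fold higher with TAp63γ. PHGDH, the first enzyme of serine synthesis, was 4.99-fold higher with TAp63γ than with p53 and 4.24-fold higher with the hybrid than with p53. Of 15 heat shock genes, 4 were higher and 0 lower with p53, 6 and 1 with TAp63γ, and 5 and 3 with the hybrid, with medians of 0.01, 0.06 and 0.00, which became -0.23, -0.35 and -0.49 with equal array medians. The small heat shock protein gene CRYAB was at least 61.6-fold higher with p53, at least 32.4-fold with TAp63γ and at least 54.4-fold with the hybrid, and BAG3, a co-chaperone, was 4.74-fold, 6.07-fold and 4.33-fold higher. Genes of the osteoblast lineage went both ways. Of 22 measured, 6 were higher and 6 lower with p53, 7 and 7 with TAp63γ, and 6 and 7 with the hybrid, with medians of 0.16, 0.23 and 0.01 that turned to -0.12, -0.06 and -0.42 with equal array medians. SP7, the osteoblast transcription factor osterix, was 18.3-fold lower with TAp63γ and 12.4-fold lower with the hybrid. SPP1, which encodes osteopontin, was below the floor with GFP and p53, and was at least 31.2-fold higher than with GFP with TAp63γ and at least 68.7-fold with the hybrid (SD 3.89 in log2 over 2 probe sets). RUNX2 was 3.59-fold lower with p53 (SD 1.04 over 5 probe sets).

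Matrix and signalling lists also held single large differences. Of 33 matrix, adhesion and angiogenesis genes, 6 were higher and 3 lower with p53, 6 and 5 with TAp63γ, and 7 and 4 with the hybrid, with medians of 0.25, 0.03 and 0.43 within the random range, the last pair turning to -0.04 and -0.04 with equal array medians. COL18A1 was 10.7-fold, 11.8-fold and 21.7-fold higher, and the metalloproteinase inhibitor gene TIMP3 was 7.33-fold, 7.82-fold and 9.32-fold higher. Against TAp63γ, the median of this list with the hybrid was 0.43 at percentile 99.8. Of 29 Notch, Wnt, Hedgehog and FGF genes, 5 were higher and 4 lower with p53, 5 and 6 with TAp63γ, and 9 and 6 with the hybrid, with medians of 0.11 (-0.14 with equal array medians), 0.00 and 0.57. SPRY1, a feedback inhibitor of FGF signalling, was 5.30-fold, 12.2-fold and 15.1-fold higher. Of 21 housekeeping and ribosomal genes, 1 was higher and 0 lower with p53, 1 and 1 with TAp63γ, and 1 and 3 with the hybrid. Their medians of 0.23, 0.46 and 0.51 lay within the random range, and those for p53 and the hybrid both turned to -0.08 with equal array medians. Among markers of other cell types, endothelial genes were 3 higher and 0 lower of 10 with p53 and likewise with TAp63γ, with medians of 0.13 and 0.41. Blood cell markers were 1 higher and 0 lower with p53 and 3 and 0 with TAp63γ of 12, with medians of 0.36 and 0.33, and kidney epithelial and neural markers 1 and 1 with p53 and 2 and 1 with TAp63γ of 10, with medians of 0.20 and 0.37.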
